A study of Mus musculus with 4 samples.

How the data were processed

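RNA of sorted bone marrow HSCs from naive C57/BL6 mice was measured on a NanoString nCounter panel in 4 pools of 3 mice each, per the labels. Cells were sorted directly into a phenol-based lysis reagent and total RNA was extracted, per the labels' protocols. The surface markers used for the sort, the name of the code set, its control probes and the authors' normalization steps are not given in the sources used here. The labels' extraction text speaks of mice with ICH or sham surgery at day 3, against naive and healthy in the titles, the diagnosis and the series text. Samples were grouped by their titles into 1 group, with the replicate numbers of the titles, and each pool counted as 1 replicate.

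The deposited table holds the signal of 561 genes in 4 columns, as normalized counts. What the authors did was worked out from the values alone. In each sample, 100% of the values above 20 were whole multiples of one step to within 0.02 count, with steps of 1.43, 1.20, 1.08 and 1.14 in replicates 1 to 4, so that each value is a probe count times a factor of its sample. The 14 housekeeping genes were identified from the values, by a geometric mean of 622 in every sample. A scaling on these genes is thus inferred from the same values and is not given by the labels. Counts under 20 stand in the table as exactly 20 without the factor, since the lowest value above 20 was 20 counts in each sample. On the normalized scale this floor ends at 28.7, 24.1, 21.6 and 22.8 in replicates 1 to 4, so it differs between samples, and values at 20 have no order. Dividing by the step gave the probe counts of all values above the floor. Their sums per sample ran from 80657 to 103616, and their medians were 58, 58, 64.5 and 95, over different numbers of genes. By exact Poisson limits (95%), a count of 20 has an interval of 12.2 to 30.9, a count of 100 of 81.4 to 122, and a count of 1000 of 939 to 1064. These intervals cover counting error only. The 3 highest genes took 22.1, 23.7, 22.4 and 21.0% of a sample's signal.

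Gene names were used as in the table and matched to a table of mouse genes (assembly GRCm38.p6) for names and gene types only. Of the names 545 were current symbols, 14 were matched by a synonym and 2 were not matched. No coordinates are given, since the table names no genome build. Columns left unused numbered 0.

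A gene was above background in a sample if its value exceeded 20 (20 counts). Levels are mean ± SD of the deposited values over 4 pools, given only where all 4 lay above background. The spread is the SD of log2(value + 1). Counting noise was tested per gene by 100000 multinomial draws of its recovered counts over the 4 samples, with chances set by the scaling factors and a chi-square statistic. This Monte Carlo multinomial test is two-sided in effect and rests on that counting model with fixed factors. Its p was adjusted by Benjamini-Hochberg over the 323 endogenous genes above background in all 4 samples, with housekeeping genes adjusted apart. This test had been planned for count tables only, and running it on recovered counts was decided after the data were seen. The level of a list was described by the percentile of its median among 10000 random lists of its size from the endogenous genes. Joint variation of a list was tested, one-sided, by permutation over genes: the variance over samples of the members' mean deviation was set against 10000 random lists matched on level in 5 bins, with lists of at least 5 detected members adjusted together. The gap test divides the distance of an extreme replicate to its neighbour by the whole range, and Dixon's 95% critical value for 4 samples was used. Pairs of replicates differed by more than sampling of counts, with a chi-square over its degrees of freedom between 2.50 and 8.35, so that no 2 samples were counted as 1. Whether pools were processed on different days is not given in the sources used here, and the p-values set genes against counting error (noise test) or against other genes (list test), not against the spread between pools.

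The gene lists covered the stem and progenitor cell, haematopoietic transcription factors, granulocyte and monocyte, B cell, T cell, NK and innate lymphoid cell, dendritic cell and antigen presentation, erythroid with megakaryocyte and platelet, mast cell with basophil and eosinophil, endothelial and stromal cell, sensing receptors, NF-kB, JAK-STAT, interferon response, interleukin and growth factor, their receptors, chemokine, chemokine receptor, TNF superfamily, complement, apoptosis, cell cycle, the Notch, Wnt and TGF-beta pathways, adhesion and housekeeping. Named genes were the 15 endogenous genes of highest mean, the 15 of largest and the 5 of smallest spread among those above background in all 4 samples with a mean of at least 4 times the background (80), and for each list the 4 highest members above background in all 4 samples and, by alphabet, the first 3 below it in all 4. Ties were broken by alphabet and housekeeping genes were left out of the first 3 parts. The groups, these lists, the rule for named genes and the main settings were fixed before the data were examined, as were most alternatives. Lists of 28 genes of other tissues, 18 neutrophil genes and 13 interferon-stimulated genes were added after the data were seen, as were 2 further backgrounds, a scaling without Gapdh and a filter on list members. Housekeeping genes named in the report outside this rule were chosen after their values were seen. Some genes that the rule selects are not reported here.

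The noise test was checked on simulated counts of the 323 genes. It called 74% of 100 genes changed 1.5-fold in 1 of 4 samples, 99% of 100 changed 2-fold and 3.25% of 123 unchanged genes. The simulation held counting error only, with exact scaling factors. It also changed most genes, whereas 31 of 323 were called in the data. These rates therefore need not hold for the data. In 100 simulated lists of 10 genes the list test passed 5 with no shift and 70 with a log2 shift of 0.3 in 1 sample, unadjusted. Deviations were shuffled within each gene there, which removes any variation between pools that genes share. In the data 21 lists were also adjusted together, so these list rates need not hold there either. Alternatives were other backgrounds, other scalings (total, housekeeping list, geometric mean of detected genes), other pseudocounts (0.5 and 10), filters on low values, other summaries of a list, and leaving out each replicate in turn. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.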

Results

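Haematopoietic stem cells (HSCs), the marrow cells from which all blood lineages arise, were sorted by flow cytometry from the bone marrow of naive C57/BL6 mice, and their RNA was counted with a NanoString nCounter panel, in which a barcoded probe pair counts the molecules of each target without amplification. The samples form 1 group of 4 pools, each pool holding the cells of 3 mice, so that the pool is the replicate and 12 mice were used in all. The panel held 561 genes. Of these, 14 housekeeping genes were inferred from the values to carry the scaling between samples, and 547 were endogenous targets. The probe counts above the floor of the table summed to 80657, 91941, 103616 and 92962 in replicates 1 to 4. With a single group there is no contrast between conditions. The data therefore give the level of each gene, the spread of that level between pools, and the genes whose pools differed by more than counting error. The label on RNA extraction speaks of mice with ICH or sham surgery at day 3, while the sample titles, the diagnosis and the series title give naive, healthy animals. The titles were followed here, and the conflict remains open.

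Among endogenous genes, those outside the 14 inferred to carry the scaling, B2m, the light chain of MHC class I molecules, had the highest normalized count, at 7985 ± 292 (SD, n = 4). S100a8 and S100a9, which encode the subunits of calprotectin, followed at 3624 ± 1363 and 2993 ± 1330 (SD, n = 4). Arhgdib stood at 2492 ± 163, and Cd34, a sialomucin of stem and progenitor cells, at 1639 ± 115 (SD, n = 4). The invariant chain Cd74 stood at 1552 ± 53.3, the MHC class II chain H2-Aa at 1285 ± 133 and the MHC class I chain H2-K1 at 1175 ± 78.3 (SD, n = 4). Further genes among the 15 highest were Ifitm1 (1181 ± 11.4), Spn (1107 ± 63.8), Mif (991 ± 28.9), Ctnnb1 (904 ± 80.6), Itgb1 (854 ± 52.1), Jak1 (826 ± 24.4) and Cd81 (819 ± 43.4), as mean ± SD of 4 pools. Probes of different genes differ in how well they capture their target, so an order of genes is an order of probe counts and not of transcript numbers.

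Of the 561 genes, 337 (60.1%) lay above the background of 20 counts in all 4 replicates, 152 in 1 to 3 replicates and 72 in none. The 337 genes comprised 323 of the 547 endogenous genes and 14 of the 14 housekeeping genes. The number of genes at the floor was 140, 94, 109 and 212 in replicates 1 to 4, and 65 genes were at the floor in replicate 4 alone. Counts of detected list members therefore depend on that replicate. Without replicate 4, 24 of the 25 gene lists had at least 50% of their measured members above background, against 19 with all 4 replicates. A value of 20 is a bound, so genes at the floor are given without a mean. With a background of 50 counts, 214 genes remained above it in all 4 replicates. None of 28 genes typical of liver, gut, lung, kidney, brain or other tissues outside the blood, a list drawn up after the data were seen, lay above the floor in all 4 replicates, but 7, 14, 11 and 0 of them did so in replicates 1 to 4, with highest values of 57.4, 71.1, 39.9 and 20. With values at the floor taken as 20, the mean plus 2 SD of these 28 genes was 40.4, 50.6, 32.4 and 20. In replicate 4 all 28 stood at the floor, so the value of 20 there is the floor itself. Genes at such levels, as in several lists here, are close to background.

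Markers of the stem and progenitor state were nearly all detected. Of the 9 measured genes of that list, 8 were above background in all 4 replicates, and the list's median level lay at percentile 99.9 of 10000 random lists of its size from the panel. Cd34 stood at 1639 ± 115, the stem cell factor receptor Kit at 444 ± 19.1, the tetraspanin Cd9 at 425 ± 43.2 and the integrin Itga6 at 367 ± 28.6 (SD, n = 4). Of 26 haematopoietic transcription factors, 15 were above background in all 4 replicates and 1, Maf, in none. The highest were Tal1 (551 ± 35.3) and Runx1 (486 ± 51.4), both needed to form HSCs, followed by Ets1 (189 ± 9.49) and Ikzf2 (174 ± 18.1), as mean ± SD of 4 pools. The erythroid, megakaryocyte and platelet list had 5 of 6 measured members above background, led by the transferrin receptor Tfrc (700.5 ± 45.9), Cd9 and the megakaryocyte integrin Itga2b (223 ± 25.7). In the mast cell, basophil and eosinophil list 3 of 6 members were above background in all 4 replicates, and the other 3 were so in 3 replicates each. Apart from Kit, the levels of those above it in all 4 were low, with Il1rl1 at 61.2 ± 16.9 and Fcer1g at 53.8 ± 10.1 (SD, n = 4).

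Markers of mature lineages were detected to an extent that varied from list to list. The dendritic cell and antigen presentation list had 21 of 28 measured members above background and a median at percentile 99.97 of random lists. Another 5 members were above background in 1 to 3 replicates only, and Psmb11 and H2-Ea-ps were below it in all 4. The highest members were the antigen presentation genes B2m, Cd74, H2-Aa and H2-K1, so the list's level is not a measure of dendritic cell markers alone. The B cell list had 14 of 18 members above background (percentile 86.1, and 54.85 for detected members set against other such genes), with Cd74 at 1552 ± 53.3, Cd24a at 804 ± 112, the antigen receptor component Cd79b at 373 ± 29.6 and Xbp1 at 317 ± 32.2 (SD, n = 4), while the recombinase Rag1 was below background throughout. The granulocyte and monocyte list had 15 of 28 members above background and a median at percentile 28.4 (7.25 for detected members alone, and 56.05 by the mean), although S100a8, S100a9, Camp (601 ± 320) and Ctsg (537 ± 256) were its highest members, and the macrophage receptors Marco and Msr1 were below background in all 4 replicates. The T cell list had 5 of 21 members above background in all 4 replicates and 15 in 1 to 3 replicates (percentile 1.66). Its highest members were Lck at 77.1 ± 7.10 and Cd2 at 69.4 ± 3.11 (SD, n = 4). The natural killer (NK) and innate lymphoid list had 2 of 21, Cd244 (48.8 ± 4.14) and Il2rb (46.6 ± 13.6), levels that genes of other tissues also reached in replicates 1 and 2. Another 8 members were above background in 1 to 3 replicates, and Fasl, Gzma and Ifng were among its 11 members below background in all 4 replicates. Of 12 endothelial and stromal genes 6 were above background, with the niche chemokine Cxcl12 at 242 ± 37.8 and Pecam1 at 215 ± 22.5 (SD, n = 4).

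**Figure D1:**
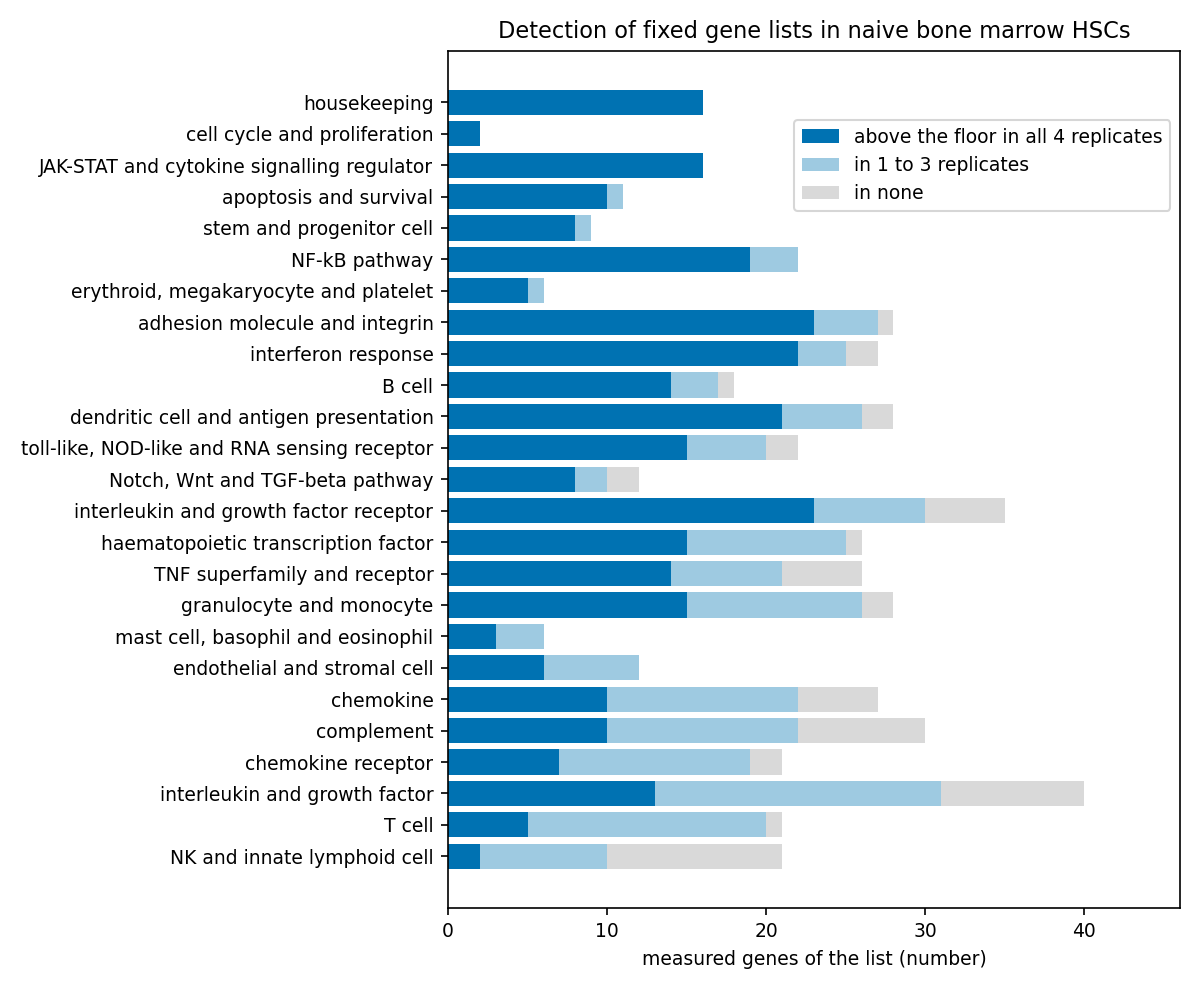
Number of measured genes of each of 25 gene lists (horizontal axis) that lay above the floor of 20 counts in all 4 replicates (dark bars), in 1 to 3 replicates (light bars) or in none (grey bars). Of the JAK-STAT list 16 of 16 members were above the floor in all 4 replicates, against 2 of 21 of the NK and innate lymphoid list.

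Signalling lists were detected to different extents. All 16 measured members of the JAK-STAT list were above background in all 4 replicates, with Jak1 at 826 ± 24.4, Ptpn6 at 492 ± 28.9, Stat3 at 431 ± 31.4 and Stat5b at 336 ± 7.58 (SD, n = 4). The NF-kB list had 19 of 22 members above background, led by Nfkb1 at 418 ± 27.7, and the apoptosis list had 10 of 11, with Casp8 at 340.0 ± 16.3 (SD, n = 4). The interferon response list had 22 of 27, with Ifitm1, Mx1 (707 ± 303) and Tap1 (499 ± 11) the highest, while Ifng and Ifi204 were below background in all 4 replicates. The adhesion list had 23 of 28, led by Spn and Itgb1, and the Notch, Wnt and TGF-beta list had 8 of 12, led by Ctnnb1 and by Tgfb1 at 747 ± 48.0 (SD, n = 4). The sensing receptors (toll-like, NOD-like and RNA sensing) had 15 of 22, with the RNA sensors Ddx58 at 312 ± 11.6 and Ifih1 at 237 ± 5.83 (SD, n = 4), and Tlr5 and Nod2 below background. Of the 2 measured cell cycle genes, Abl1 stood at 85.0 ± 4.62 and the inhibitor Cdkn1a at 84.6 ± 29.8 (SD, n = 4).

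Of 40 interleukins and growth factors, 13 were above background in all 4 replicates (percentile 1) and 18 in 1 to 3 replicates. Mif and Tgfb1 were followed by Ltb (350.1 ± 20.2) and Ebi3 (290 ± 14.4), while Csf2, Il10 and Il1rn were below background throughout. Receptors of interleukins and growth factors were detected in 23 of 35 cases (percentile 70.4), with Kit, Crlf2 (340.4 ± 24.2), Il17ra (325 ± 29.3) and Il10rb (179 ± 26.1) the highest, as mean ± SD of 4 pools. Of 27 chemokines 10 were above background, led by Cxcl12 and Ccl3 (204 ± 20.5), and of 21 chemokine receptors 7, where Cxcr4, the receptor of Cxcl12, stood at 303 ± 20.1 and the next, Ccr7, at 47.2 ± 3.66 (SD, n = 4). The TNF superfamily had 14 of 26 members above background, with the cytokine Ltb and the receptor Cd27 (346 ± 15.3) the highest. The complement list had 10 of 30 (percentile 1.02, and 14.4 for detected members alone), led by C1qbp (767 ± 20.8), C1qb (185 ± 4.49) and Cd55 (158 ± 14.3), and C7 and C8a were among its 8 members below background in all 4 replicates. The 16 measured genes of the housekeeping list were above background in all 4 replicates. A total of 7 lists lay in the top 2.5% of random lists, namely stem and progenitor cell, dendritic cell and antigen presentation, NF-kB, JAK-STAT, interferon response, Notch, Wnt and TGF-beta, and adhesion. When each list was held to its members above background and set against other such genes, 3 lists did so (stem and progenitor cell, antigen presentation and JAK-STAT). The NF-kB list then lay at percentile 47.6, the interleukin list at 43.7, the list of their receptors at 11.9 and the T cell list at 8.4.

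Most genes varied little between the pools. Among endogenous genes with a mean of at least 80, the smallest spreads included those of the phosphatase Ptpn2 (112 ± 1.05), Ifitm1 (1181 ± 11.4), Stat6 (302 ± 2.95) and Stat5a (291 ± 4.58), as mean ± SD of 4 pools. Their coefficients of variation (0.941, 0.965, 0.977 and 1.58%) lay below those of counting alone (10.4, 3.21, 6.34 and 6.46%), so these low spreads do not mark the genes as steadier than others. The largest spreads were those of Ifna1, Camp, Tnfrsf11a, Mx1, Ctsg, S100a9 and S100a8, whose highest replicate exceeded the lowest by between 2.41-fold (S100a8) and 5.06-fold (Ifna1). Over the 323 endogenous genes above background in all 4 replicates, the median SD of log2(value + 1) was 0.153, and 80% of the genes fell between 0.059 and 0.393. The median coefficient of variation between pools was 10.6%, and the median of the values set by the Poisson variance of the counts was 10.4%. In the 197 genes with a mean of at least 80 these medians were 8.14% and 7.97%. An SD of 4 pools lies below the true SD more often than above it. The near-equal medians therefore do not show that counting alone explains the spread. Across the 337 genes above background, which are not independent replicates, pairs of replicates had a Pearson correlation of log2 values between 0.973 and 0.986 and a Spearman correlation between 0.958 and 0.975.

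The genes of largest spread beyond counting noise followed different orders of the replicates. S100a8 had normalized counts of 5354, 2218, 3985 and 2938 in replicates 1 to 4, S100a9 of 4666, 1741, 3433 and 2130, and the antimicrobial peptide gene Camp of 1026, 277, 643 and 457. The granule protease gene Ctsg had another order, at 276, 443, 546 and 883. Mx1, an interferon-induced gene that the C57BL/6J annotation lists as a transcribed pseudogene, stood at 918, 954, 657 and 299. Ifna1 (188, 213, 161 and 42.2) and Tnfrsf11a, the receptor of the osteoclast factor RANKL (181, 198, 140 and 59.3), had their lowest value in replicate 4 as Mx1 did. The Ifna1 probe may share its target with other interferon alpha genes, of which the annotation lists 14 coding members, so its value is uncertain.

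In all, 31 of the 323 genes differed between the pools by more than counting noise after Benjamini-Hochberg adjustment, and 76 did so at an unadjusted p under 0.05. Each gene was tested by Monte Carlo draws of its counts over the replicates from a multinomial model. For S100a8, S100a9, Camp, Ctsg, Mx1, Ifna1 and Tnfrsf11a the unadjusted Monte Carlo p was 1e-05, the smallest that the draws can give. After adjustment this Monte Carlo p was 0.000323. The highest replicate exceeded the lowest by 2-fold or more in 15 of the 31 genes, and by less than 1.5-fold in 13, such as B2m (1.09-fold), Arhgdib (1.16-fold), Cd34 (1.18-fold) and H2-Aa (1.26-fold). The test takes the scaling of each sample as exact, although counting error alone gives the housekeeping factor a standard error of 1.75 to 2.05%. Of the 31 genes 12 were lowest and 11 highest in replicate 4. With the geometric mean of all detected genes as the scaling, 57 genes were called, 9 lowest and 41 highest in replicate 4. The housekeeping scaling without Gapdh, chosen after the data were seen, tilted the other way, with 36 genes called, 20 lowest and 9 highest in replicate 4. Without replicate 4 the count was 9, of which 8 were among the 31: B2m, Camp, Cdkn1a, Cybb, Ctsg, Mx1, S100a8 and S100a9.

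Of the 15 genes named for the largest spread, Cybb, Cdkn1a, Irak2 and Lcp2 also passed the test, with means of 82.9 ± 27.3, 84.6 ± 29.8, 87.8 ± 23.4 and 218 ± 51.5 (SD, n = 4). Phlpp2 (87.9 ± 19.9), Ifngr2 (92.5 ± 19.2), Csf3r (133 ± 25) and Ski (97.3 ± 19.1) did not. By list, 5 of the 15 tested granulocyte and monocyte genes passed (8 when adjusted over the list alone), and 5 of the 21 tested antigen presentation genes (6 when adjusted over the list alone). None of the 16 JAK-STAT genes passed by the adjustment over all genes or when adjusted over the list alone. Among the stem and progenitor genes Cd34 passed (2 genes when adjusted over the list alone), with a range of 1.18-fold. Of the 14 housekeeping genes 5 passed when adjusted over these 14. Gapdh had the largest difference, at 10344, 11528, 9617 and 7102 in replicates 1 to 4, so that it was 1.47-fold lower in replicate 4 than in the other pools.

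**Figure D2:**
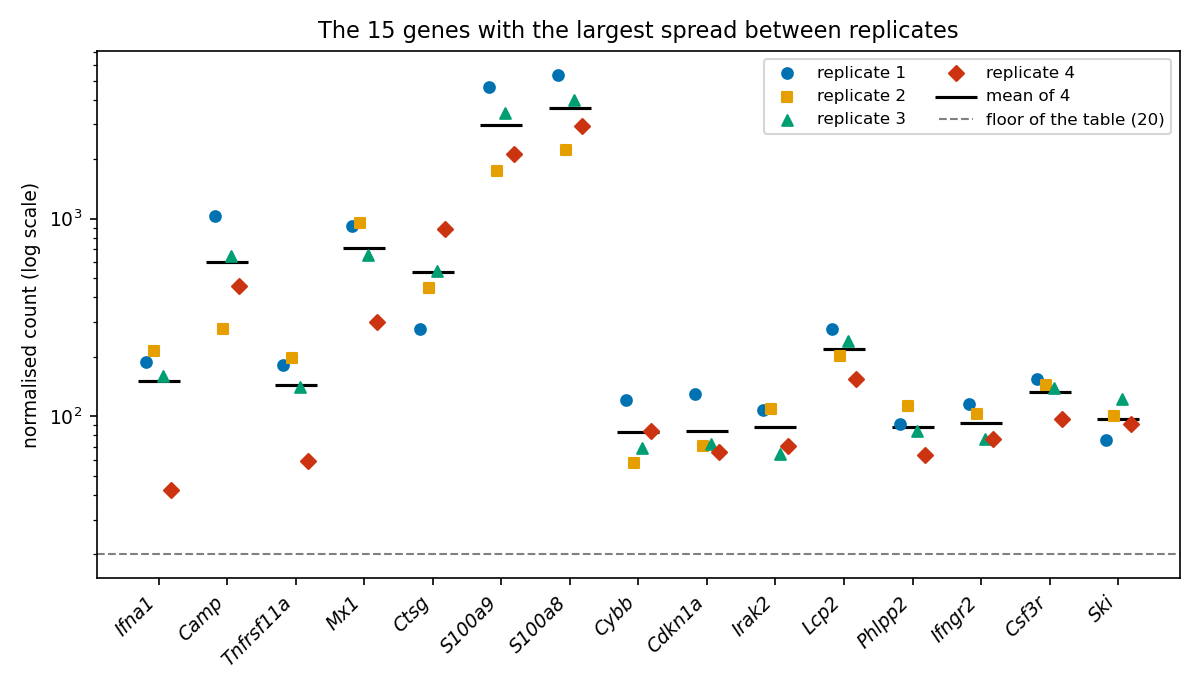
Normalized counts (vertical log axis) of the 15 genes with the largest spread between pools (horizontal axis), with a marker for each of the 4 replicates, a black line at their mean and a dashed line at the floor of 20. Ifna1, Tnfrsf11a and Mx1 were lowest in replicate 4 (42.2, 59.3 and 299), whereas S100a8, S100a9 and Camp were highest in replicate 1 and lowest in replicate 2.

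Low and high genes deviated in opposite directions in replicate 4. Among the 68 genes with a mean between 40 and 60, replicate 4 lay below the gene's own mean by a median log2 deviation of -0.23, and replicates 1 and 2 lay above it by 0.12 and 0.15. Among the 34 genes with a mean between 400 and 1000, the median deviation was 0.10 in replicate 4 and -0.06 in replicate 2. Of the 11 called genes that were highest in replicate 4, 8 had a mean between 400 and 1000, among them Cd24a, Ctnnb1, Itga4 and Runx1.

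**Figure D3:**
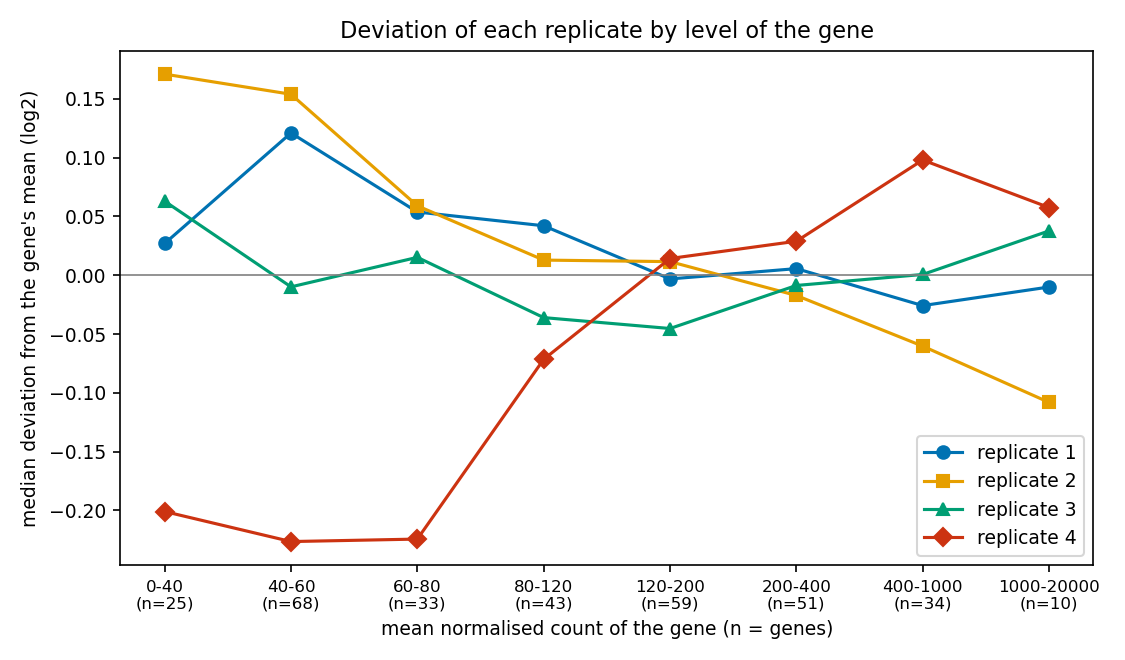
Median deviation of each replicate from the gene's mean over 4 replicates (vertical axis, log2) for endogenous genes above the floor, in bins of mean normalized count (horizontal axis, with the number of genes in each bin). Replicate 4 lies at -0.23 in the bin from 40 to 60 and at 0.10 in the bin from 400 to 1000.

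No gene list moved together between the pools beyond random lists of like level. Of 21 lists with at least 5 detected members, 0 passed a one-sided permutation test over genes after Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. These were the interferon response list (permutation p = 0.013, adjusted p = 0.273) and the chemokine list (permutation p = 0.0275, adjusted p = 0.289). The mean deviation of the interferon list was 0.07, 0.12, -0.03 and -0.17 (log2) in replicates 1 to 4, and that of the chemokine list 0.09, 0.21, 0.02 and -0.31. Mx1 and Ifna1 carried most of the interferon list's value in replicate 4, since the other 20 members had mean deviations of 0.03, 0.07, -0.05 and -0.05. The granulocyte and monocyte list had an adjusted p of 0.379 by this permutation test, and it passed (adjusted permutation p = 0.0048) when only members with a mean of at least 80 were used, a setting chosen after the data were seen.

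A gap test for 1 replicate standing apart from the other 3 was made on 125 values, and 6 (4.8%) exceeded the 95% critical ratio, about the 1 in 20 that chance gives. They were the levels of Cdkn1a, Ifitm1, Il17ra and Tnfsf10 and the mean deviations of the JAK-STAT and chemokine receptor lists.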

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

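The 7 tests of explanations given here were all chosen after the results they address had been seen, whereas the gap test itself was planned. In 6 of 125 values the gap ratio of 1 replicate exceeded the critical value, and chance gives about 1 in 20. The level of Cdkn1a, an inhibitor of the cell cycle, had a gap ratio of 0.869 with replicate 1 highest (129 against 66.1 to 72.2). For Ifitm1 the ratio was 0.830 with replicate 2 lowest, although its 4 values lay between 1164 and 1189. Il17ra had a ratio of 0.848 with replicate 4 lowest. Tnfsf10 had a ratio of 0.859 with replicate 4 highest (217 against 167 to 174). The mean deviation of the JAK-STAT list (gap ratio 0.835) and of the chemokine receptor list (0.847) was lowest in replicate 4, at -0.027 and -0.24 (log2).

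Replicate 4 had lower values for genes near the floor. In the number of genes at the floor its gap ratio was 0.610, under the critical value, so it was not shown to stand apart. The same held for the number of genes at or above a normalized level of 28.7 (gap ratio 0.542). A lower depth of that sample is argued against: at one common normalized level of 28.7, which all samples resolve, replicate 4 held 325 genes against 390 to 445 in the others, whose SD was 27.6. A signal added to all probes, smaller in replicate 4, stays open: of 28 genes of other tissues 0 reached that level in replicate 4, against 7, 11 and 2 in replicates 1 to 3, with two-sided Fisher exact p = 0.0102, 0.000288 and 0.491, so that replicates 3 and 4 were not shown to differ. In 312 genes, a line of replicate 4 on the mean of the others had an intercept of -12.93 normalized counts and a slope of 1.082. The bootstrap 95% interval of this intercept was -17.05 to -8.21, over genes and not over pools. Like lines for replicates 1 to 3 had intercepts of 6.19, 9.63 and 1.12, with slopes of 0.982, 0.944 and 0.972. These lines restate the pattern and do not part an added signal from weaker expression. No biological explanation was tested, since the design names no difference between the pools, and weaker expression of many low genes stays open beside a lower background.

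Mx1, Ifna1 and Tnfrsf11a were lower in replicate 4 than in the other pools by 2.79-, 4.41- and 2.89-fold. Their gap ratios (0.679, 0.824 and 0.714, with replicate 4 lowest) were under the critical value. A weaker interferon response of the size of the Mx1 difference is argued against by 13 other interferon-stimulated genes, whose median log2 difference was 0.0213 (SE 0.0225, range -0.20 to 0.20), such as Ifitm1 at 1189 in replicate 4. A signal of equal size on every probe is argued against as well, since the smallest difference of the 3 genes was 114 normalized counts where 34.1, 2 times the lower bound of the intercept, was the limit. A probe-specific signal that moves with the low genes stays open: 3 of the 3 genes rank the replicates as the number of genes at the common level does, but among 194 other genes with a mean of at least 80, 9 (4.64%) share that order where chance gives 4.17%, and the 3 were picked for their low value in replicate 4. A true difference of these transcripts between pools stays open too, untested.

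S100a8, S100a9 and Camp were higher in replicate 1 than in replicate 2 by 2.41-, 2.68- and 3.70-fold. Scaling of whole samples is argued against by 194 other genes with a mean of at least 80, whose median log2 difference between these replicates was 0.00567 (SE 0.0165). RNA of mature neutrophils in different amounts, which the sort for HSCs would be meant to remove, cannot be told apart from a change within the sorted cells: 10 of 18 listed neutrophil genes were measured above the floor, 7 of the 10 were higher in replicate 1, and their median log2 difference was 0.0525 (SE 0.069, range -0.10 to 1.06). The most abundant of them, Csf3r (154 and 143), Tyrobp (131 and 137) and Itgb2 (123 and 133, in replicates 1 and 2), differed less than Cybb (121 and 57.8), which had the direction of S100a8, and Tyrobp and Itgb2 were chosen after their values were seen; 11 of the 18 genes are also in the granulocyte and monocyte list. Ctsg, a protease of granulocyte precursors, had the other direction, at 276 in replicate 1 and 443 in replicate 2.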

How the results depend on the processing

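Among the settings here, the common-level and other-tissue backgrounds, the scaling without Gapdh and the filter on list members were chosen after the data were seen. The number of genes above background was 337, and 214 at 50 counts, by the stricter threshold. It was 318 at the common level, 283 with a background from other tissues (floor values taken as 20) and 407 when 3 replicates sufficed. It was 338 to 402 with each replicate left out. By the mean it was 489, but counts under 20 stand as 20, so any 1 replicate above the floor sufficed there. The median SD of log2 values was 0.153, and 0.172 with the geometric mean of detected genes as scaling. That scaling also raised the genes beyond counting noise from 31 to 57 (28 shared). It raised replicate 4 by 0.092 (log2), and 41 of the 57 genes were highest in that replicate, against 11 of the 31. The cause was not tested beyond these values. The spread was 0.118 with a mean of at least 4 times background, a filter that removes genes of high counting error, and 0.144 to 0.152 with a replicate left out. Genes beyond counting noise numbered 9 to 32 with a replicate left out: 9 without replicate 4, and 23, 31 and 32 without replicates 2, 1 and 3; the cause was not tested. They numbered 42, 32 and 36 with total, housekeeping list and Gapdh-free scaling, with 29, 30 and 28 shared. Of the 31 genes 24 were called under all 4 other scalings, and 5 also without any single replicate: Camp, Ctsg, Mx1, S100a8 and S100a9. Lists in the top 2.5% numbered 7, and 3 with detected members alone. The 19 lists with at least 50% of members detected became 13 to 24. Lists moving together numbered 0, and 1 (granulocyte and monocyte) with members of mean at least 80; its adjusted permutation p ran from 0.0048 to 0.743, and the cause was not tested. The concordance calls of single lists stayed on their side in the other 225 cases, level percentiles kept their side in 130 cases and moved in 14, and detected members stayed within 1.5 times in 183 cases and moved in 42. Values with a replicate standing apart numbered 6, and 4 to 7 under other scalings. No paired analysis was possible because there is 1 group. Backgrounds of 10 counts, TMM and dispersion models, and the noise test without a filter were not run, since counts under 20 are not in the table. The gap test was not run with a replicate left out. Depth limits the genes near the floor, where 20 counts have an interval of 12.2 to 30.9.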

Other observations

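The genes of this part were picked after their values were known, and the noise test on recovered counts was chosen after the data were seen. Genes of the B cell surface were detected in these sorted HSCs. Cd79b stood at 373 ± 29.6 and Ms4a1 at 184 ± 16.3 (SD, n = 4), both above the floor in all 4 replicates. Cd79a, the partner of Cd79b in the B cell receptor, was at the floor in replicates 1 and 4 and reached 28.9 and 23.7 in replicates 2 and 3. The adjusted p of the noise test for Ms4a1 and Cd79b was 0.566 and 0.352, by Monte Carlo multinomial draws, so these levels were not shown to differ between pools. Whether the pools held B cells was not tested.

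Slamf1, a gene of the most primitive HSCs, stood at 45.3 ± 7.13 and Cd48, a gene of later progenitors, at 96.5 ± 15.3 (SD, n = 4). The complement genes C1qa (148 ± 12.6) and C1qb (185 ± 4.49), known from macrophages, were detected in all 4 replicates, as were the macrophage genes Cd163 (65.4 ± 11.5), Emr1 (65.2 ± 14.6) and Csf1r (49.0 ± 13.5), while Marco and Msr1 were at the floor in all 4. Genes of other tissues reached up to 57.4 and 71.1 in replicates 1 and 2, so the levels of Slamf1, Cd163, Emr1 and Csf1r are close to background.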
